A study of Mus musculus with 7 samples.

How the data were processed

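Messenger RNA levels were measured on 7 one-colour oligonucleotide arrays of the Affymetrix MOE430_2 design, hybridised with biotin-labelled RNA, per the labels. The arrays fall into a floxed group with 2 arrays, a deleted group with 3 arrays and a re-expressed group with 2 arrays, and the labels assign each array to experiment 1 or experiment 2. Experiment 1 has 1 array of each group, and experiment 2 has 1 floxed array, 2 deleted arrays (2a and 2b) and 1 re-expressed array. The labels do not say whether arrays 2a and 2b came from separate cultures, nor whether the other arrays of a group did, so the p-values measure only the spread between these arrays, which may be technical.

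The deposited values are intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5 and give no version or settings. Some deposited values lie below 0, which a plain MAS5 signal does not take, so the exact summary method behind the intensities stays open. The table has 45101 probe sets, of which 64 are control probe sets. Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and were left unnamed, and 9160 were not listed with a gene. The gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and no symbol had to be updated. That table served for gene names and for the order of neighbouring genes; no genome build is given in the sources used here for the array, and no coordinates are printed.

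The means of the deposited intensities between the 2nd and 98th percentiles differed 1.74-fold between the highest and lowest array, more than the 5% set as tolerance, so the arrays were quantile-normalized. Values were then floored at 1, a pseudocount of 56.1 (the 25th percentile of all normalized values) was added, and log2 was taken. A log2 difference is therefore on the log2(signal + pseudocount) scale, which understates changes of dim genes. The probe set with the highest mean log2 value over the 7 arrays stood for its gene. Of 18193 genes with a probe set, the 9097 at or above the median of that mean were tested. The 10092 probe sets with several symbols or none were fitted apart as a check. Of the 3295 among them above the median, 0 passed the limma threshold in any comparison. At an unadjusted p under 0.05 there were 86, 111 and 25, where 164.75 would be by chance. That fit had no term for the experiment, so differences between experiments widened its spread, which can lower such counts.

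Comparisons were fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with 1 coefficient per group, all 7 arrays in the fit and 4 residual degrees of freedom. The prior degrees of freedom were 2.57. All tests are two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 9097 genes. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 24 lists that had enough measured members, and again with an estimated correlation and with fry. An eosinophil list had too few measured members to be tested. The lists held 627 genes, 577 of them with a probe set, and covered blood lineages, the cell cycle, stress, signalling and metabolism.

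The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names Tal1 and Mef2c in each comparison, the 10 genes with the largest change per direction (5 for re-expressed minus floxed) among those past the threshold with the same sign in both experiments, and at most 4 members per list past the threshold. Where fewer passed, the genes with the smallest p filled each direction up to 5, with their adjusted p and without being called changed. Further list members given as examples are those with the smallest p in their list and were chosen after their values were seen.

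Experiment numbers come from the labels and mark arrays run as 1 experiment, so they pair arrays across groups. Deviations of arrays from their group means correlated across genes at 0.262 to 0.860 in the 8 pairs of arrays from 1 experiment and different groups, and at -0.146 for deleted 2a with 2b, which share a group mean. The sources used here state no statistical model, so the main model had no term for the experiment, and the fit with that term is given where it changes a call.

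The scripts were tested on simulated data built from the real gene means and spreads, with 200 of 9097 genes changed per draw over 20 draws. For deleted minus floxed, 24.1% of genes changed by 1 on the log2 scale were recovered, 67.9% of those changed by 2 and 90.9% of those changed by 4, with 0.25 false calls per draw. For re-expressed minus deleted the shares were 23.9%, 67.1% and 91.1%, with 0.6 false calls per draw. A list of genes shifted by 0.8 was called in 20 of 20 draws with both the preset and the estimated correlation. Simulated genes were independent, so this does not test the handling of correlated genes. With 200 genes changed per draw, the Benjamini-Hochberg threshold is easier to reach than with the few changed genes called below. The shares may therefore overstate recovery in the real data.

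Alternatives were the values as deposited, centring on the median, another pseudocount, another filter on dim genes, no intensity trend, array weights, all probe sets, the experiment as a block, arrays 2a and 2b averaged, only the groups compared, and each array left out in turn. For arrays, precision is limited by their number. Technical summaries per array were taken from the control probe sets of the deposited table.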

Results

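Gene expression was measured in a mouse megakaryocytic cell line with, without and again with the transcription factor Scl. Scl, encoded by Tal1, is a basic helix-loop-helix protein required for blood formation, and megakaryocytes are the bone marrow cells that release platelets. The parent line was derived from fetal liver progenitors of E12.5 embryos, in which both Scl alleles carry loxP sites. It was immortalised with a Hox11 retrovirus and is clonal; its cells looked like megakaryocytes and had acetylcholinesterase activity, an enzyme of mouse megakaryocytes. A retrovirus carrying the Cre recombinase removed Scl (deleted line), and a second retrovirus carrying Scl was then put into the deleted cells (re-expressed line). All cells received thrombopoietin, the main growth factor of megakaryocytes, for 5 days before harvest. The comparisons ask which genes depend on Scl in these cells, and which return to their former level when Scl is put back.

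The 7 arrays differed in brightness by experiment. Median deposited intensities were 187 to 194 in experiment 1 and 80.3 to 106 in experiment 2, with the lowest value in array deleted 2a. In that array 5.68% of probe sets lay below 1, against 0.616% to 1.72% in the others. After normalization the first principal component, with 56.0% of the variance, separated the experiments, and the second, with 24.8%, set deleted 2a apart. Correlations across genes, which are not independent replicates, were 0.961 to 0.973 within experiment 1, 0.926 to 0.968 among the other arrays of experiment 2, and 0.856 to 0.919 between deleted 2a and those arrays. The 3' over 5' ratio was 1.03 to 1.09 for actin and 0.918 to 0.983 for Gapdh in all arrays, while that of the transferrin receptor was 3.37 to 7.63, highest in deleted 2a. A probe set for the middle of 18S ribosomal RNA read 1861 in deleted 2a and 100 to 291 in the others. The TrpnX control probe set also stood apart there, at 1818 against 38.7 to 645, so the high reading was not limited to 18S. The Cre control probe set read 7970 to 12283 in all 7 arrays, including the floxed ones, so it gives no information on the retroviral Cre. Among sex-linked genes, all below the filter, normalized signals were 80.5 to 135 for Xist, lowest in floxed 2. Floxed 2 also read lowest for Eif2s3y (33.6 against 149 to 400 in the other arrays). The same held for Kdm5d (31.8 against 59.6 to 168) and Uty (145 against 161 to 358). The cause was not tested.

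By its probe set, Tal1 was high in the floxed cells, low in all deleted arrays and unevenly restored. Its normalized signal was 3020 and 2930 in the floxed arrays of experiments 1 and 2, 127, 120 and 167 in the deleted arrays, and 295 and 2038 in the re-expressed arrays. The log2 difference was -3.97 for deleted minus floxed (standard error 0.67, limma adjusted p = 0.284), with -4.07 in experiment 1 and -3.91 in experiment 2. It was 2.15 for re-expressed minus deleted (standard error 0.67, adjusted p = 0.752), with 0.94 and 3.40, and -1.82 for re-expressed minus floxed (adjusted p = 1.00), with -3.13 and -0.51. None of these passed the threshold in the fit of all arrays, whose shared spread includes the gap between the 2 re-expressed arrays. Without re-expressed array 1 or 2, the deletion difference was -4.02 (adjusted p = 0.00271) and -3.96 (adjusted p = 0.00316); with only the 2 groups compared its adjusted p was 0.00294. Without re-expressed array 1, re-expressed minus deleted was 3.48 (adjusted p = 0.0236), and without re-expressed array 2, re-expressed minus floxed was -3.10 (adjusted p = 0.0436). Whether the probe set lies in the deleted part of the gene, or is present in the retroviral copy, was not checked here. Genes that fell on deletion, described below, rose again in both experiments. Shares turned back are given here as ratios of log2 differences, not of signals. The share of their deletion change turned back in experiments 1 and 2 was 110% and 111% for Gng11 and 81.2% and 83.3% for Myct1. It was 85.6% and 94.7% for Gnaq and 66.6% and 113% for Vwf. In experiment 1, the Vwf signal was 1716 in the re-expressed and 6512 in the floxed array. Since these genes rose again in experiment 1 too, the Tal1 signal of 295 need not measure the Scl made from the retrovirus.

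**Figure D1:**
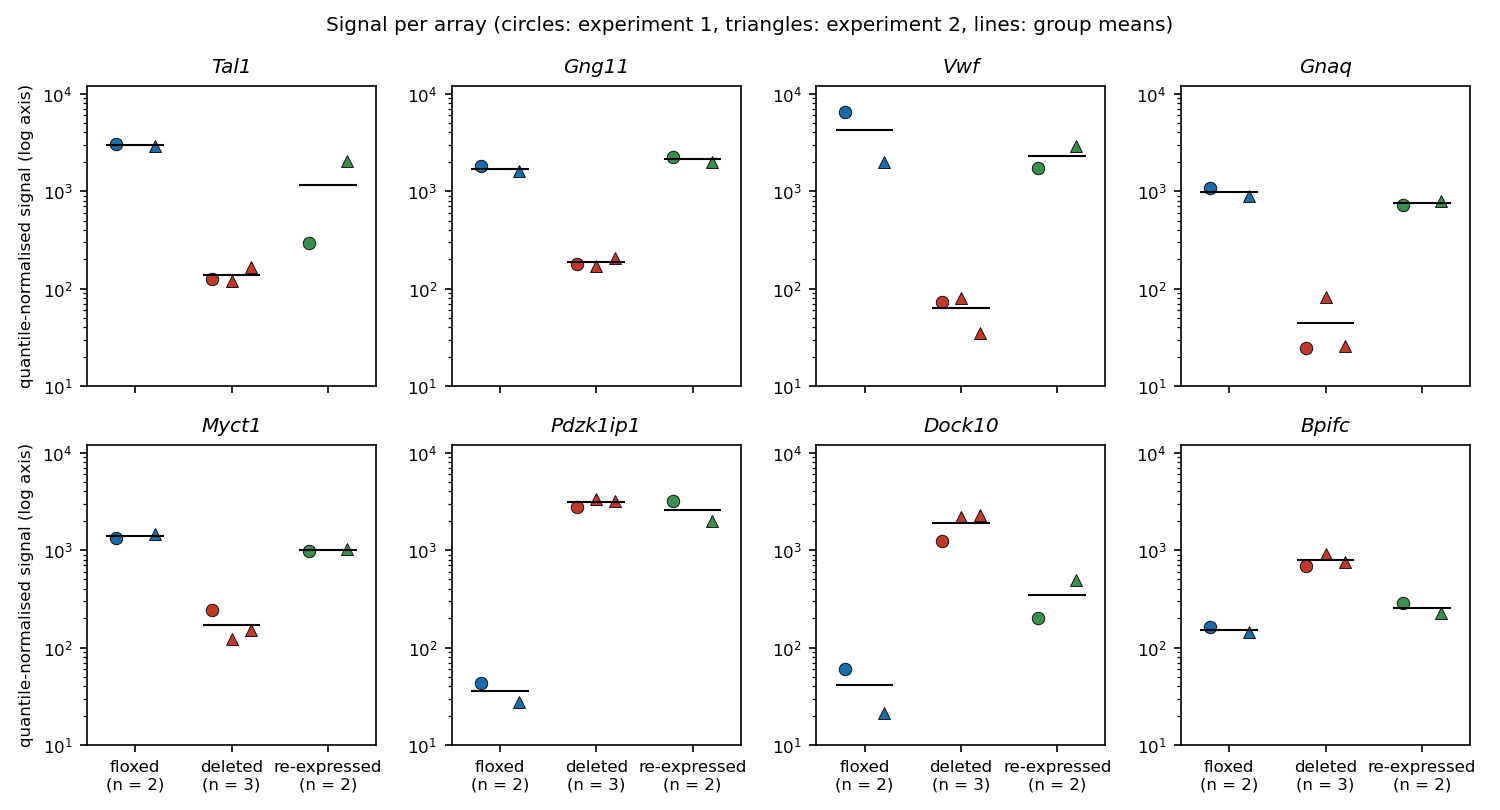
Quantile-normalized signal, on a log axis, of 8 genes in each of the 7 arrays, grouped as floxed (n = 2), deleted (n = 3) and re-expressed (n = 2), with circles for experiment 1, triangles for experiment 2 and lines for the group means. Gng11, Vwf, Gnaq and Myct1 sit low in all 3 deleted arrays, Dock10 and Bpifc sit high there, and Pdzk1ip1 stays high in both re-expressed arrays.

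Vwf, Gnaq, Gng11 and Myct1 fell on deletion of Scl, and Pdzk1ip1, Dock10 and Bpifc rose. Of the 9097 genes, 7 changed, 3 higher and 4 lower. At an unadjusted p under 0.05 in limma there were 531, where 454.85 would be by chance, and 728 with the experiment as a block. Without the block, differences between experiments add to the spread, so 454.85 is not a firm chance level. Vwf, the platelet adhesion protein von Willebrand factor, fell from a normalized signal of 4248 ± 3201 (SD, n = 2) to 63.0 ± 24.2 (SD, n = 3). Its log2 difference was -4.96 (standard error 0.50, adjusted p = 0.0462). Gnaq, the G protein alpha subunit Gq, fell by 3.42 on the log2 scale (standard error 0.28, adjusted p = 0.0257). Gng11, a G protein gamma subunit, fell from 1702 ± 145 to 185 ± 16.5, a log2 difference of -2.86 (standard error 0.13, adjusted p = 0.00115). Myct1 fell by 2.72 (standard error 0.23, adjusted p = 0.0281). Upward, Pdzk1ip1, a small membrane protein gene, rose from 35.6 ± 10.9 to 3099 ± 303, a log2 difference of 5.11 (standard error 0.22, adjusted p = 0.00115). Dock10, a guanine nucleotide exchange factor, rose by 4.31 (standard error 0.41, adjusted p = 0.0389), and Bpifc by 2.00 (standard error 0.18, adjusted p = 0.0335).

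All 7 genes kept their direction in both experiments. In experiments 1 and 2 the log2 differences were -5.66 and -4.19 for Vwf, -3.81 and -3.16 for Gnaq, -2.97 and -2.77 for Gng11, and -2.21 and -2.999 for Myct1. They were 4.82 and 5.31 for Pdzk1ip1, 3.47 and 4.88 for Dock10, and 1.76 and 2.15 for Bpifc. Leaving out any 1 of the 7 arrays kept the calls of Gng11 (adjusted p 0.00564 to 0.0335) and Pdzk1ip1 (0.000903 to 0.0287). The calls of the other 5 genes were lost without 5 to 7 of the arrays, with adjusted p up to 0.233 for Vwf, 0.179 for Gnaq, 0.278 for Myct1 and 0.298 for Dock10 and Bpifc. Genes next in line by p, which did not pass, were Gbp8 (2.76, adjusted p = 0.0789), Napsa (1.91, adjusted p = 0.0850) and Armcx1 (-1.50, adjusted p = 0.180). Mef2c differed by -0.66 (standard error 0.65, adjusted p = 0.874), with -2.22 in experiment 1 and 0.33 in experiment 2. On the same probe set with 1 array left out it differed by -1.09 to -0.11. All other probe sets of Mef2c were lower on deletion in both experiments. They differed by -2.54 to -0.91 in experiment 1 and by -1.13 to -0.050 in experiment 2.

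The megakaryocyte and platelet list fell on deletion in the test with a preset correlation between genes. Its 28 measured genes had a mean log2 difference of -0.79, and 6 of them were above 0 (camera adjusted p = 4.27e-05; with an estimated correlation adjusted p = 0.663; with fry adjusted p = 0.195). The median was -0.37. The mean was -1.06 in experiment 1 and -0.56 in experiment 2, where 10 of the 28 genes were above 0. Gng11 and Vwf passed over all genes, and 4 members passed when adjusted over the list alone: these 2, Cavin2 (-1.97) and Plek (-4.27), a platelet protein kinase C substrate. The G2 and mitosis list also fell, with a mean of -0.42 and 1 of 29 genes above 0 (adjusted p = 0.000604; with an estimated correlation adjusted p = 0.727). That shift came mostly with array deleted 2a, the one with the 18S signal of 1861: without it the mean was -0.040 (adjusted p = 0.426), against -0.64 without deleted 2b, and the call was also lost without floxed array 1 (adjusted p = 0.154). In deleted 2a minus deleted 2b the list differed by -1.17, with 0 of 29 genes above 0, and the S phase list by -0.76.

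Smaller upward shifts were seen for cholesterol synthesis and class I antigen presentation. The cholesterol synthesis list rose by 0.18 on average, with 17 of 20 genes above 0 (adjusted p = 0.00501; with an estimated correlation adjusted p = 0.663), led by Msmo1 (0.58) and Sqle (0.33). The class I antigen presentation list rose by 0.26, with 8 of 11 genes above 0 (adjusted p = 0.0128; with an estimated correlation adjusted p = 0.727), led by the peptide transporter gene Tap2 (0.80). No member of either list passed over all genes. Without floxed 2 the cholesterol synthesis mean was 0.29. Both calls were lost without floxed array 1, at means of 0.072 and 0.16 (adjusted p = 0.422 and 0.249), and the class I call also without deleted 2a (0.0859) or 2b (0.0769). With the experiment as a block, p53 targets (adjusted p = 0.0327), immediate early genes (0.0148) and TGF beta signalling (0.0148) passed as well, which makes 7 lists against 4. With that block and an estimated correlation their adjusted p was 0.697, 0.697 and 0.666.

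Among the lists that did not pass on deletion, the partners of Scl and other hematopoietic transcription factors had a mean of -0.071 (adjusted p = 0.896). Markers of other blood lineages had means of -0.024 for erythroid, 0.15 for mast cell and basophil, -0.38 for neutrophil, -0.18 for macrophage, 0.53 for B lymphoid and 0.22 for T and NK lymphoid genes, with adjusted p from 0.109 to 0.896. Stem and progenitor genes (-0.014), fetal liver and stroma (-0.0049), S phase (-0.19), D cyclins and inhibitors (-0.13), interferon response (0.15), platelet cytoskeleton (-0.097), glycolysis and hypoxia (-0.21), the unfolded protein response (-0.078), STAT5 targets (-0.032) and heme and iron (-0.067) did not pass either. The mean, the median and the test did not share a sign for the erythroid, neutrophil, stem and progenitor, fetal liver and STAT5 lists. Over their list alone, Runx1 (-0.70), Ighm (0.91), Mycn (0.50), Slc2a3 (-1.79), Pfkp (-0.99) and Pim1 (0.58) passed. The other probe sets of Mycn gave 0.23 and -0.0017.

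**Figure D2:**
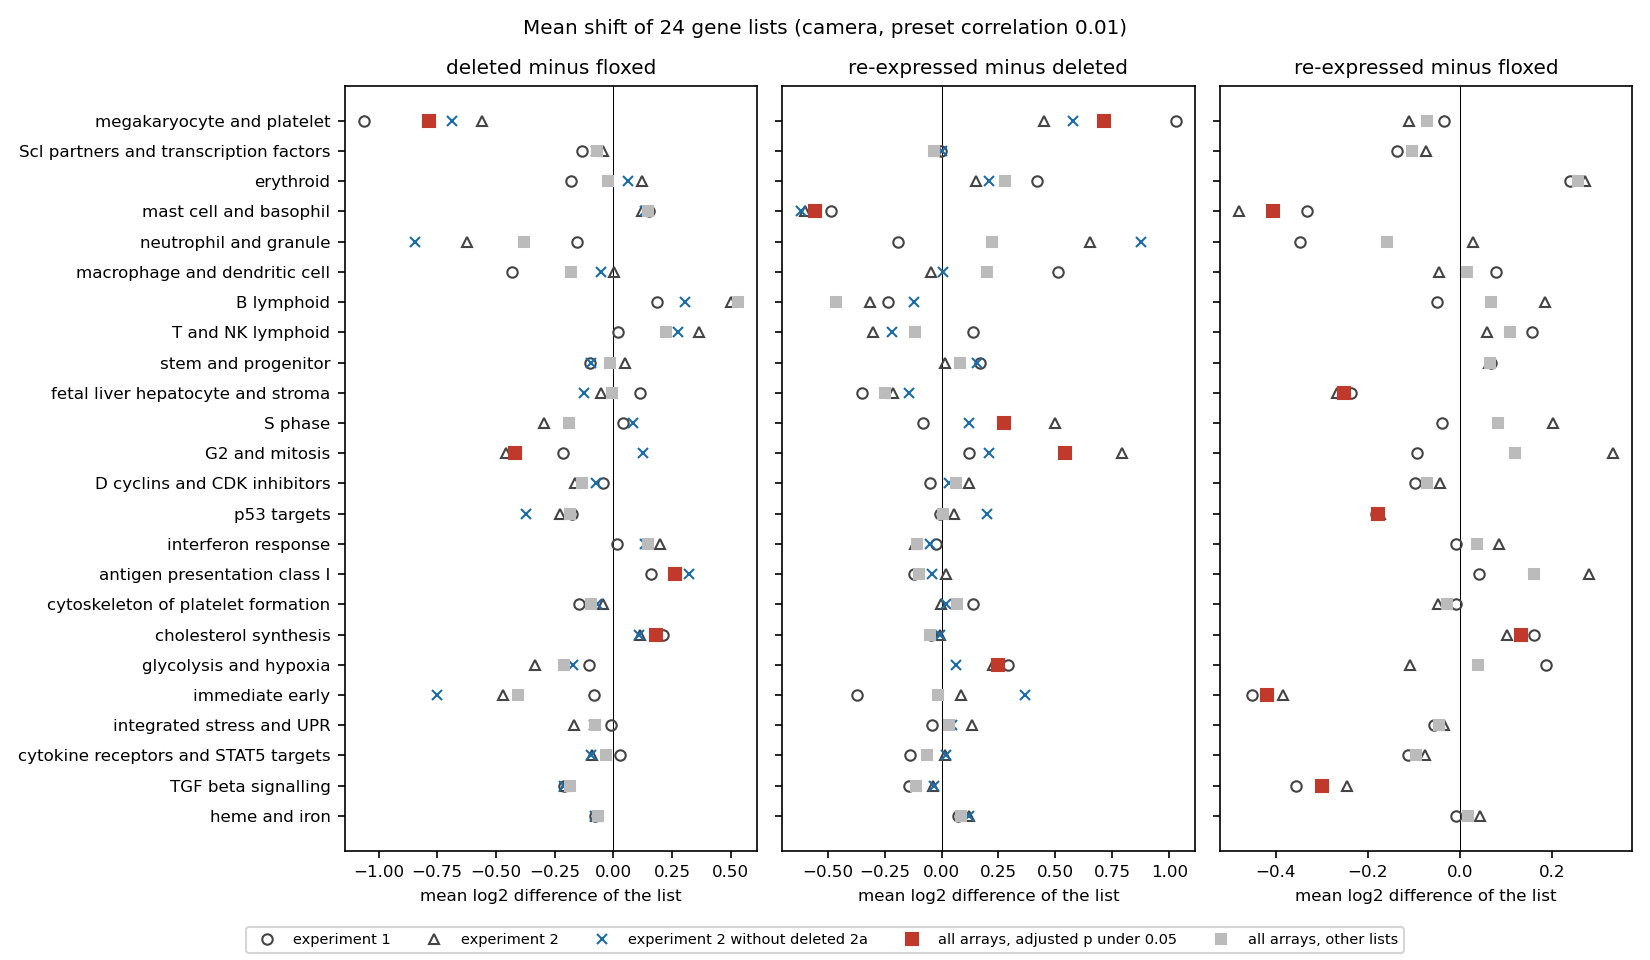
Mean log2 difference of the measured members of 24 gene lists in 3 comparisons, with squares for all arrays (red where the camera adjusted p is under 0.05), circles for experiment 1, triangles for experiment 2 and crosses for experiment 2 without deleted 2a. The megakaryocyte and platelet list lies below 0 on deletion (-0.79) and above 0 on re-expression (0.71), and the crosses of the G2 and mitosis list lie away from its squares.

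Gng11 rose when Scl was put back. It was the only one of 9097 past the threshold, rising from 185 ± 16.5 (SD, n = 3) to 2129 ± 174 (SD, n = 2), a log2 difference of 3.18 (standard error 0.13, adjusted p = 0.00117), with 3.28 in experiment 1 and 3.08 in experiment 2. At an unadjusted p under 0.05 there were 511 genes, and 653 with the experiment as a block, against 454.85 by chance. The next genes by p were 3 others that had fallen on deletion, none past the threshold in all arrays: Gnaq (3.06, adjusted p = 0.0775), Myct1 (2.26, adjusted p = 0.119) and Vwf (4.29, adjusted p = 0.198). Each was higher in both experiments, and each passed without 1 array: Gnaq without deleted 2a (0.00935), Myct1 without deleted 1 (0.0342) and Vwf without floxed 2 (0.0481). Below 0 lay Itgb7 (-1.29, adjusted p = 0.218), an integrin chain of lymphoid and mast cells, Bpifc (-1.43, adjusted p = 0.218) and Gzmb (-1.35, adjusted p = 0.235), the protease granzyme B, which passed without re-expressed 2 (0.0188). Myo1c (0.76), Gatad2a (-0.75) and Glul (-0.77) had an adjusted p of 0.288. Mef2c differed by 0.78 (adjusted p = 0.858), with 2.54 in experiment 1 and -0.43 in experiment 2, and 0.22 to 1.43 on the same probe set with 1 array left out. All other probe sets of Mef2c were higher on re-expression in both experiments. They rose by 1.14 to 3.14 in experiment 1 and by 0.16 to 1.73 in experiment 2.

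The megakaryocyte and platelet list rose on re-expression and the mast cell and basophil list fell. The first rose by 0.71 on average, with 19 of 28 genes above 0 (camera adjusted p = 0.00669, and 0.809 with an estimated correlation). Its median rose by only 0.15. The mean rose by 1.03 and 0.45 in experiments 1 and 2, with 22 and 15 of the 28 genes above 0. Over the list alone, 3 members passed upward and 1 downward. Without deleted 1 (adjusted p = 0.0918) or re-expressed 1 (mean 0.46, adjusted p = 0.612) its call was lost. The mast cell and basophil list fell by 0.56, with 1 of 10 genes above 0 (adjusted p = 9.9e-04; with an estimated correlation adjusted p = 0.353; with fry 0.00370), and by 0.49 and 0.60 in the experiments. The median of the mast cell and basophil list was -0.16. With no filter on dim genes the list fell by 0.22 (camera adjusted p = 0.0444). Gzmb and Cyp11a1 (-2.16) passed when adjusted over the list alone.

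Cell cycle genes rose as well on re-expression, again with array deleted 2a and its 18S signal of 1861. G2 and mitosis genes rose by 0.54, with 28 of 29 above 0 (adjusted p = 1.09e-06; with an estimated correlation adjusted p = 0.809), and by 0.15 without deleted 2a, still called. S phase genes rose by 0.27, with 25 of 28 above 0 (adjusted p = 0.00669; with an estimated correlation adjusted p = 0.847), and by 0.019 without deleted 2a (adjusted p = 0.759); the call was also lost without re-expressed 2 (mean 0.17, adjusted p = 0.203). Glycolysis and hypoxia genes rose by 0.25, with 15 of 21 above 0 (adjusted p = 0.0370; with an estimated correlation adjusted p = 0.809), led by the glucose transporter gene Slc2a3 (1.66) and Pfkp (0.87); the call was lost without deleted 1, re-expressed 1 or deleted 2a, with adjusted p up to 0.401. In the erythroid list, 3 of 11 genes passed when adjusted over the list alone, Sptb (1.23), Urod (0.45) and Hbb-y (3.19), while the list mean of 0.28 did not pass (adjusted p = 0.480). In other lists that did not pass, Id2 (-1.58), Ighm (-0.75), Angpt1 (-0.42), Mycn (0.33) and Sox4 (0.68) also passed over their list alone. The other probe sets of Mycn lay below 0 here, at -0.31 and -0.26, so its rise rests on 1 probe set. With the experiment as a block, fetal liver and stroma genes passed too (adjusted p = 0.0312; with an estimated correlation adjusted p = 0.798). The other lists had adjusted p of at least 0.0642 in the fit without it.

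The deletion and re-expression effects share the deleted arrays, which alone gives opposite signs. Across genes their correlation was -0.794, and 100 simulations of unchanged groups gave -0.773 on average, from -0.792 to -0.753. The covariance was -0.0979 against a simulated -0.0861, from -0.0943 to -0.0797, a difference of -0.0118. Opposite signs were seen in 78.7% of genes against a simulated 78.4%, from 77.1% to 79.5%. These simulations carried the difference between experiments but drew genes independently. A test chosen after seeing the data used noise that kept the correlation between genes. There, 68 of 100 draws had a correlation at or below the observed one and 31 a covariance at or below it. That noise was mixed from only 3 residual patterns of these data, and its correlations ran from -0.998 to 0.393. So wide a range does not decide whether the observed correlation is unusual. Gng11 was the only gene that changed on deletion and back on re-expression, where independent lists would share 0.000769 genes and the simulations gave 0. The first of these figures leaves out the shared arrays and the second leaves out the effects, so neither is the chance level for both together. With no array in common, the correlation was -0.35 between deletion in experiment 1 and re-expression in experiment 2, and -0.014 the other way round. With the deleted arrays of experiment 2 split, it was -0.63 and -0.37.

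**Figure D3:**
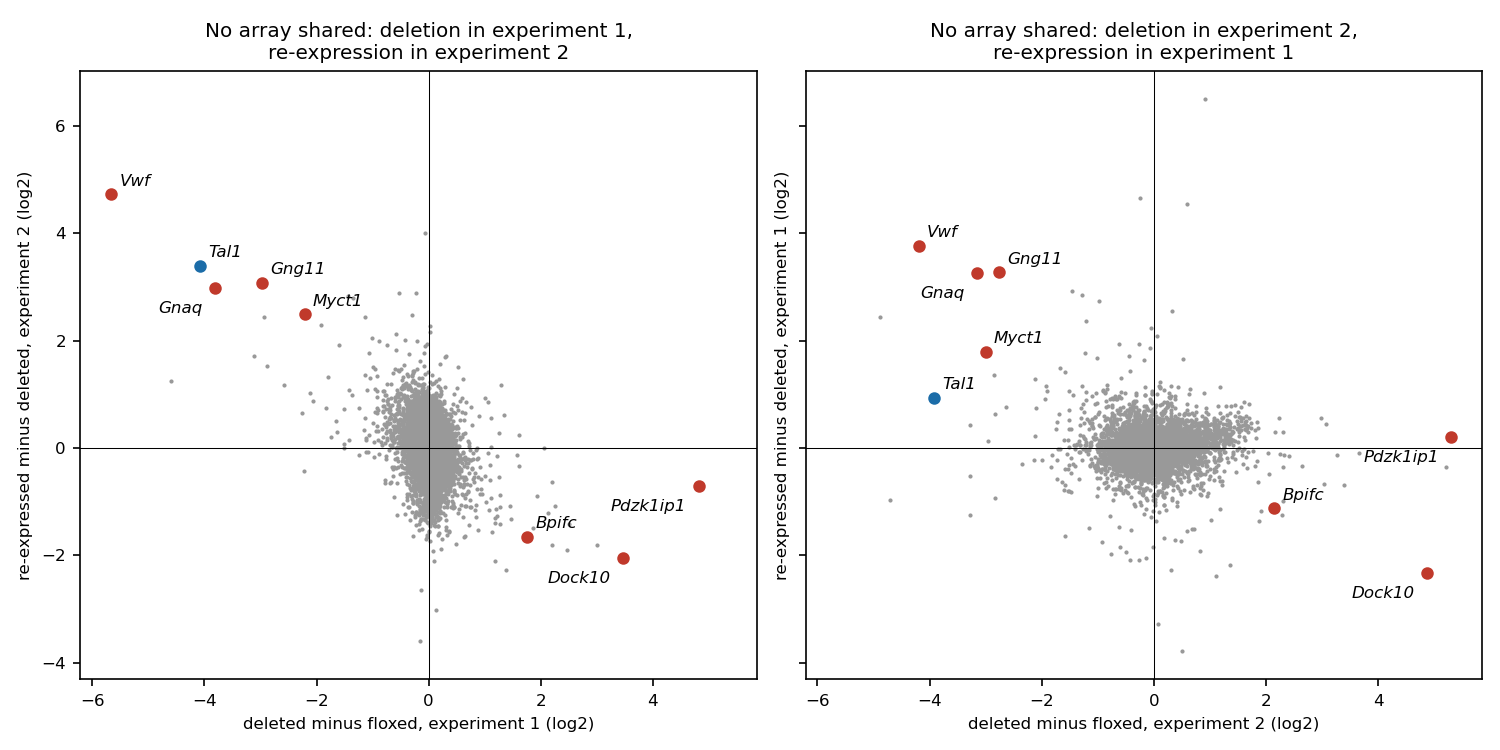
Log2 difference of each of 9097 genes on deletion (horizontal) and on re-expression (vertical), each panel taking the 2 effects from different experiments so that no array is shared, with the 7 genes changed on deletion in red and Tal1 in blue. Gng11, Vwf, Gnaq and Myct1 lie at the upper left in both panels, and Pdzk1ip1 lies far to the right near 0 on the vertical axis.

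After Scl was put back, 1 gene passed the threshold against the floxed cells. Pdzk1ip1 was 2587 ± 857 (SD, n = 2) in the re-expressed cells against 35.6 ± 10.9 (SD, n = 2), a log2 difference of 4.82 (standard error 0.24, adjusted p = 0.00352), with 5.03 and 4.60 in the experiments. Its call was lost without floxed 2 (adjusted p = 0.0602) and with only the 2 groups compared (Pdzk1ip1 4.82, adjusted p = 0.395). At an unadjusted p under 0.05 there were 160 genes, and 240 with the experiment as a block, fewer than the 454.85 by chance. Differences between experiments widen the spread of the fit without the block. Its low count therefore does not show that the groups are alike. Next by p were the oncogene Mycn (0.83, adjusted p = 0.319), Sphk2 (1.16), Gbp8 (2.02) and Fbxo7 (1.17), then below 0 Gatad2a (-0.75), Gzmb (-1.04), Cd84 (-0.82), Fxyd5 (-1.33) and Osbpl3 (-0.81), all of these after Mycn with an adjusted p of 1.00. Mef2c differed by 0.11 (adjusted p = 1.00), with 0.33 and -0.10. The other probe sets of Mycn gave -0.075 and -0.26 in this comparison. Dock10, which had risen on deletion, did not pass but lay 1.98 above the floxed cells. Its signals in experiments 1 and 2 were 200 and 493 in the re-expressed arrays and 60.9 and 21.1 in the floxed arrays. With 2 arrays against 2, a gene that did not pass may still differ.

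Immediate early genes lay lower in the re-expressed than in the floxed cells. They fell by 0.42 on average, with 2 of 17 above 0 (adjusted p = 6.5e-05; with an estimated correlation adjusted p = 0.600), led by the transcription factor genes Klf6 (-0.65) and Fosl2 (-0.69). The mast cell and basophil list fell by 0.41 (3 of 10 above 0, adjusted p = 0.00804; with an estimated correlation adjusted p = 0.317), and the TGF beta signalling list fell by 0.30 (2 of 11 above 0, adjusted p = 0.00804; with an estimated correlation adjusted p = 0.317), led by Id2 (-1.36). Fetal liver and stroma genes fell by 0.25 (1 of 6 above 0, adjusted p = 0.0298; with an estimated correlation adjusted p = 0.414; with the experiment as a block adjusted p = 0.0592), and p53 targets fell by 0.18 (1 of 15 above 0, adjusted p = 0.0209; with an estimated correlation adjusted p = 0.668). The cholesterol synthesis list rose by 0.13 (16 of 20 above 0, adjusted p = 0.00943; with an estimated correlation adjusted p = 0.600). Immediate early genes had a mean of -0.26 without re-expressed 2 (adjusted p = 0.0529), which ended the call, and of -0.23 without floxed 1, which did not. The TGF beta call was lost without re-expressed 1 (mean -0.070, adjusted p = 0.266). The cholesterol synthesis call was lost without floxed 1 (mean 0.022, adjusted p = 0.865) or re-expressed 2 (mean 0.050, adjusted p = 0.434), and its mean was 0.24 without floxed 2 and 0.22 without re-expressed 1. Without 5 of the 7 arrays each, p53 targets and fetal liver genes were not called, with means as near 0 as -0.056 (without floxed 2; -0.10 without re-expressed 1) and -0.15 (without deleted 1). The megakaryocyte and platelet list differed by -0.072 (adjusted p = 0.140), and no other list passed, with adjusted p of at least 0.0562. With the experiment as a block, class I antigen presentation also passed, at a mean of 0.16 (adjusted p = 0.0130; with an estimated correlation adjusted p = 0.563).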

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

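The block without deleted 2a, the correlations between experiments and the following of genes from 1 experiment to the other were chosen after seeing the data. Under 20 alternatives each, Pdzk1ip1 and Gng11 kept their direction and their deletion call, and Gng11 its re-expression call. The cause of the differences below was not tested unless named.

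Genes changed on deletion, 7 in all arrays, were 25 with values as deposited (9 higher, 16 lower, 6 of the 7 among them), 2 with no filter, 4 with all probe sets, 3 with 2a and 2b averaged, 4 with only the 2 groups, and 2 to 5 with an array left out (3 without deleted 2a). On re-expression, 1 gene became 19 as deposited (15 higher, 4 lower), 2 with the pseudocount at the median, 3 with no filter, 3 with array weights, 2 with all probe sets, 2 with 2a and 2b averaged, and 1 to 5 with an array left out. For re-expressed minus floxed, 1 gene became 2 as deposited, 2 with no filter, 2 with all probe sets, 0 with only the 2 groups, where 195 had an unadjusted p under 0.05 in limma, and 0 to 3 with an array left out. Genes turned back, 1, became 11 as deposited, 2 with the pseudocount at the median, 3 with array weights, 2 with 2a and 2b averaged, and 1 to 3 with an array left out. As deposited, the median of all genes moved by -0.17 on deletion and 0.15 on re-expression, so these counts are relative to that shift. The prior degrees of freedom were infinite there, against 2.57 in the main fit. Each gene thus took its spread from the intensity trend alone. Counts and p-values as deposited are therefore not comparable with those of the main fit.

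With the replicate block, 9, 1 and 1 genes changed and 1 turned back; besides adding or ending the list calls already given, it changed no other call of a named gene or list, and the 7 genes changed on deletion were among its 9. With the replicate block without deleted 2a, 10, 4 and 3 genes changed, 2 turned back and 3 lists passed on re-expression.

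The values as deposited gave limma p-values under the infinite prior named above. Tal1 on deletion was -4.18 as deposited (adjusted p = 5.4e-12), -3.97 with only the 2 groups (adjusted p = 0.00294) and -4.07 to -3.83 with an array left out. On re-expression it was 2.37 as deposited (adjusted p = 0.00512) and 0.86 to 3.48 with an array left out, and for re-expressed minus floxed -3.10 to -0.54. Mef2c in re-expressed minus floxed was 0.11, and changed sign without floxed 2, to -0.32. It was 0.82 and 0.83 without deleted 2a and 2b and 0.72 with the pseudocount at the median, where another probe set came to stand for it; the first probe set gave 0.10 to 0.11 there. The other Mef2c comparisons changed probe set in these 3 settings too, to -1.55 on deletion and 2.36 on re-expression without deleted 2a. Without floxed 1 or re-expressed 1 Mef2c lay below the filter.

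Lists called on deletion, 4, were 8 as deposited, 7 with no filter, 7 with the block, 2 to 6 with an array left out, and 0 with an estimated correlation or fry. On re-expression 5 became 3 to 7 with an array left out, 0 with an estimated correlation and 1 with fry. For re-expressed minus floxed 6 became 10 as deposited, 2 to 8 with an array left out, and 0 with an estimated correlation or fry. The correlation of -0.794 between deletion and re-expression effects was -0.63 and -0.37 with the deleted arrays of experiment 2 split, and -0.35 and -0.014 with no shared array. The alternatives ended the deletion call of Dock10 in 11 of 20, Bpifc in 13 of 19, Vwf in 13 of 20, Gnaq in 7 of 17 and Myct1 in 9 of 20, with no change of sign. Averaging 2a and 2b ended the class I call on deletion (adjusted p = 0.0712). For re-expressed minus floxed, no filter ended the calls of the mast cell (-0.13, adjusted p = 0.181) and fetal liver lists (-0.073, adjusted p = 0.244), and the latter was lost as deposited too (adjusted p = 0.0563). No filter moved TGF beta to -0.17, still called, and the deposited values moved cholesterol synthesis and class I on deletion to 0.061 and 0.15, still called. Dim genes are limited by signal over background, most in deleted 2a.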

Other observations

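In the fit with the experiment as a block, more genes passed between experiments 1 and 2 than between the groups (9, 1 and 1 genes). The experiments were compared on more arrays than the groups, which also raises their count. Over all 7 arrays, with group as a term, 434 genes differed, 266 higher and 168 lower in experiment 2, a comparison chosen after seeing the data. By the 1 probe set that stood for each gene, some had a high signal in 1 experiment and a low one in the other. Sox9 had a mean normalized signal of 31.8 in experiment 1 and 2327 in experiment 2, Bcl6b 53.5 and 2800, and Inhba 94.0 and 2647. In the other direction, Sel1l3 had 5921 and 126. Whether these differences lie in the cells or in the arrays and their processing was not tested. Class I antigen presentation genes were higher in experiment 2 by 0.31, 11 of 11 above 0 (adjusted p = 8.43e-05; with an estimated correlation adjusted p = 0.706), cholesterol synthesis genes higher by 0.17, 14 of 20 above 0 (adjusted p = 0.0288; with an estimated correlation adjusted p = 0.706), and immediate early genes lower by -0.52 (adjusted p = 0.0288; with an estimated correlation adjusted p = 0.706).

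Genes with the strongest deletion effect in experiment 1 mostly moved the same way in experiment 2. Of the 50 genes lowest on deletion in experiment 1, 45 were lower in experiment 2 (55.1% of all genes) and 44 were higher again on re-expression there (54.9% of all genes). Of the 50 highest, 42 were higher in experiment 2 (44.9% of all genes) and 41 turned back (45.1% of all genes). From experiment 2 to experiment 1, 41 of 50 kept their direction in each case, while 27 of the lower genes (46.9% of all genes) and 25 of the higher (53.03% of all genes) turned back in experiment 1. The genes were chosen and followed in different arrays, but both counts within an experiment share its deleted arrays, so they are not independent of each other.

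All 8 tests in the paragraphs that follow were chosen as tests after the results were seen, although leaving out deleted 2a was an alternative fixed before. Pdzk1ip1 stayed high when Scl was put back. Its other probe set gave 4.61 on deletion, which argues against a probe set that reads another transcript. In experiment 2, where the Tal1 signal returned to 2038, 13.3% of the deletion change of Pdzk1ip1 was turned back on the log2 scale. Its signals there were 27.9 in the floxed, 3332 and 3209 in the deleted and 1981 in the re-expressed array. The lowest of the other 6 genes was 42.0% on that scale, so Pdzk1ip1 did not return as they did. This does not decide on control by the level of Scl alone. Whether the Tal1 probe set reads the retroviral copy was not checked, and the 6 genes were chosen from these data. Pdzk1ip1 is the protein-coding gene next to Tal1 in assembly GRCm38.p6, so a change of that region kept by the deleted line may be involved. Stil, on the other side, differed by -0.51 (limma adjusted p = 0.849). Its signal was 78.7 in deleted 2a, 272 and 233 in the other deleted arrays and 285 and 267 in the floxed arrays. The Stil difference thus came mostly with deleted 2a and does not decide on a change of the region. With 1 deleted line, that explanation and a lasting effect of the loss of Scl cannot be told apart.

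The low G2 and mitosis genes of the deleted group may belong to array deleted 2a: without it the mean was -0.040 instead of -0.42. A lower signal of that array at like expression is argued against: on the values as deposited, the lowest of 10000 random lists matched on expression was -0.49 in 2a minus 2b, against -1.29 for the list. An effect of losing Scl stays open, since the list differed by 0.13 in deleted 2b minus floxed 2 and by -0.21 in deleted 1 minus floxed 1. RNA quality and hybridisation of deleted 2a were not tested as causes and stay open. There 18S read 1861 against 100 to 291 in the others, and the TrpnX control 1818 against 38.7 to 645. The transferrin receptor ratio of 7.63 was close to the 6.83 of deleted 2b, with 3.37 to 5.44 in the rest.

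Mef2c was lower on deletion in experiment 1 and not in experiment 2, by the probe set that stood for it. The other 4 probe sets were all lower in experiment 2, with a median of -0.61, so the choice of probe set may account for the difference in sign. The median over its probe sets was -0.87 in floxed 2 minus floxed 1, which leaves open a lower starting level in experiment 2. By the probe set that stood for Mef2c, deleted minus floxed was higher by 2.55 in experiment 2 than in experiment 1. The fit of that difference had 1 residual degree of freedom, from deleted 2a against 2b. It therefore cannot decide whether the experiments differed.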
